A study of Homo sapiens with 6 samples.

How the data were processed

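RNA was extracted with RNeasy columns and sequenced as Illumina libraries, per the labels' protocols, from 3 untreated and 3 treated samples of the human myeloma line RPMI 8226. Groups were taken from the sample titles and treatment labels. The labels speak of a vector in the control group, and the groups are called untreated and treated here, as in the titles.

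For each library the authors deposited a table of read counts per gene and a table of FPKM values, which are scaled to gene length and library size. STAR, an aligner, and featureCounts, a read counter, are named in the submitters' processing notes, without versions, together with the hg19 build. All 29366 genes in the deposited tables, however, carry the gene start and end of GENCODE 29, an annotation of GRCh38, so coordinates are given as in the files and named as GRCh38. Whether counting used the strand, and whether reads with several matches were counted, is not given in the sources used here. Values of overlapping and antisense genes and of close paralogs or pseudogenes are therefore uncertain. The deposited counts are whole numbers with no gene at 0 in all 6 libraries (the lowest sum was 2 counts), so genes without reads had been left out before deposit. The deposited FPKM of each gene equalled its count divided by its listed length times 1 factor per library. That factor was 1.00 to 1.01 times the value from summed counts in untreated and 0.963 to 0.969 times in treated libraries, so the FPKM carry a scaling between libraries beyond total counts.

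Library totals ran from 18519667 to 23888147 counts, with 23241 to 24326 genes detected per library, and 95.3% to 95.8% of counts were in protein-coding genes. At this depth the common biological coefficient of variation was 0.0666. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 3.16 to 7.16 over genes, against 58.8 to 70.6 between groups), and no libraries held identical values. Counts are relative: a gene's value is its share of the RNA counted, not an amount per cell. Intervals and floors given here cover counting error only, with a floor of 3 counts.

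Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with default settings left 16289 genes, TMM factors (0.977 to 0.981 in untreated and 1.02 in treated libraries) scaled the libraries, and a quasi-likelihood model with robust dispersion compared treated with untreated, without other terms. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM, counts scaled to a library of 1e6, used the same factors, and the SE of a log2 fold change was taken from the F statistic of its test. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 29 lists with at least 5 tested members, and again with an estimated correlation and with fry. Of 924 genes in 30 lists, 870 were found in the files, 39 of them by gene ID under another symbol. The lists cover ENL and its partner complexes, ENL targets in leukaemia, plasma cell and B cell genes, MYC targets, ribosomal proteins, cell cycle, apoptosis, stress responses, metabolism, interferon and NF-kB responses, lysosomes, housekeeping genes and markers of other cell types.

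The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule named MLLT1; the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 5 CPM and no overlap between groups; up to 4 members of each list with the smallest p among those past the threshold, or the 1 with the smallest p where none passed; and 20 fixed genes of myeloma and ENL biology. Some genes that the rule takes are not reported here. In the report EEF1A1, IFITM2, IFITM3, STAT2, IRF9, NFKBIA, TNFAIP3, ATF4, PHGDH, PSPH, ASNS, SLC7A11, PPP1R15A and DDIT3 stand outside this rule and were chosen after their values were seen. Alternatives were DESeq2 size factors, upper quartile scaling, library size alone, no filter on low counts, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust dispersion, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), the replicate number as a block, a test against a 1.5-fold change, a threshold of 0.01, and each library left out in turn. Removal of GC content and transcript length trends of each library, by splines with 5 degrees of freedom on the longest GENCODE 29 transcript of a gene, was added after the data were seen.

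The test was run on simulated data first, with counts drawn for the 16289 genes tested, from the means, dispersions and library sizes of this comparison. Of these genes, 200 were changed. The filter was applied again and left 16017 simulated genes, and a changed gene that it dropped counts as not recovered. At adjusted p under 0.05, edgeR recovered 42% of genes changed 1.25-fold, 56% at 1.5-fold, 76% at 2-fold and 88% at 4-fold, with 1 false call among 132. The simulated dispersions followed the trend over expression, not each gene's own value. Fewer genes changed in the simulation than were called in the data, which makes the adjustment stricter. These rates are therefore not the sensitivity of the real test. Figures were drawn with matplotlib 3.10.9.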

Results

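RNA sequencing measured gene expression in RPMI 8226 cells, a human myeloma line derived from plasma cells, which the labels describe as a B lymphocyte line from blood. The treated cultures received a compound known in the labels only by a code name, Cpd-1, for 4 days. The series title describes this treatment as a chemical knockout of ENL, a chromatin reader protein encoded by MLLT1. Each group held 3 libraries, numbered 1 to 3. Total counts were 18519667, 22378868 and 19626121 in untreated replicates 1 to 3 and 21103988, 23888147 and 22276401 in treated replicates 1 to 3. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The question was which genes changed their expression after 4 days with the compound.

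All 47 interferon response genes tested rose, with a median change of 2.60-fold. Of 37 genes of the integrated stress response, 32 fell and 2 rose, and 63 of 75 cytosolic ribosomal protein genes fell. IRF4, a transcription factor that plasma cells and myeloma cells depend on, fell from 675 ± 9.71 to 199 ± 5.56 CPM (counts scaled to library size, mean ± SD, n = 3), and MYC fell from 1138 ± 9.30 to 611 ± 20.6 CPM (SD, n = 3). MLLT1 itself did not pass the test.

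MLLT1 (ENSG00000130382, chromosome 19, 6210379 to 6279948 on GRCh38) was at 84.2, 77.7 and 77.6 CPM in the untreated libraries and at 82.6, 75.6 and 67.3 CPM in the treated libraries. The log2 fold change was -0.087 (SE 0.065, n = 3 per group, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.315). The estimate changed sign, to 0.033, once GC content and length trends were removed, and was -0.048 without untreated replicate 1, -0.16 without treated replicate 1 and -0.012 without treated replicate 3. A compound that removes the protein need not change the mRNA, so this level does not check the labels. Its paralog MLLT3, which encodes AF9, fell from 16.3 ± 1.18 to 12.985 ± 0.702 CPM (SD, n = 3, log2 fold change -0.33, edgeR quasi-likelihood adjusted p = 0.0202). That call was lost with library size scaling alone, with both FPKM fits, without untreated replicate 2 and without treated replicate 1. Of 24 genes for ENL and its partners in elongation and DOT1L complexes, 6 rose and 2 fell over all genes tested, and 5 rose and 2 fell adjusted over the list alone. Without untreated replicate 2, without treated replicate 1 and with library size scaling, 1 fell, and in both FPKM fits 3 rose and 1 fell. AFF1 and AFF4, scaffolds of the super elongation complex, rose with log2 fold changes of 0.43 and 0.30, and HEXIM1, an inhibitor of the elongation kinase CDK9, rose with 0.38. ELL fell with a log2 fold change of -0.31. The list as a whole was not called (camera adjusted p = 0.415).

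Of 16289 genes tested, 6312 (38.8%) changed, 3179 higher and 3133 lower in treated cells (edgeR quasi-likelihood test, adjusted p threshold 0.05). Of these, 1406 changed at least 2-fold, 793 higher and 613 lower, and 275 rose and 161 fell at least 4-fold. The median absolute log2 fold change over all genes tested was 0.26. Treated and untreated libraries did not overlap for 7852 genes (48.2%), where chance gives 10% for 3 libraries against 3. With scaling by library size alone the split was 3973 higher and 2537 lower, and after removal of GC and length trends it was 2968 higher and 3707 lower. The count of genes changed at least 2-fold was 404 on log2(FPKM + 1), a scale that understates the change of low genes, and 615 among genes with at least 5 CPM in 3 libraries, a filter that leaves fewer genes to test. On principal components of log2 CPM, the first component (66.1% of the variance) separated the groups, and treated replicate 3 stood apart from treated replicates 1 and 2 on the second (10.2%). Mitochondrially encoded genes took 4.48% to 4.81% of counts in untreated libraries and 5.22% to 5.76% in treated ones, and EEF1A1, the most abundant gene in every library, took 3.44% to 3.48% and 2.29% to 2.44%.

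**Figure D1:**
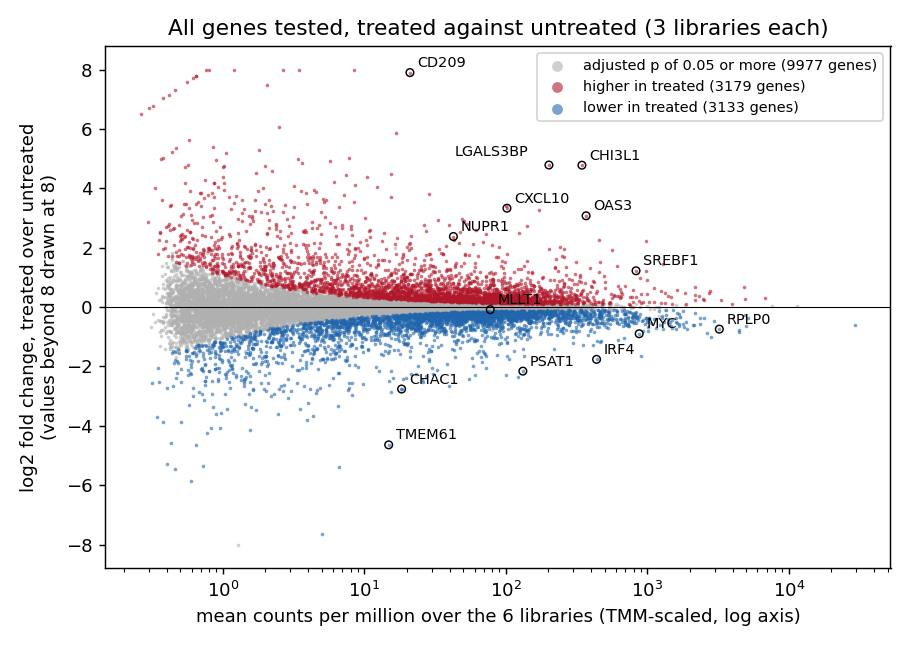
Each point is 1 of the 16289 genes tested, with its mean level over the 6 libraries in CPM on a log axis and its log2 fold change in treated over untreated cells. Red points are the 3179 genes that rose and blue points the 3133 that fell; 7 genes beyond a log2 fold change of 8 in either direction are drawn at the limit of 8.

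Of the 10 largest rises by the rule for named genes, CHI3L1, a secreted chitinase-like glycoprotein, rose from 24.2 ± 0.929 to 665 ± 0.957 CPM (SD, n = 3, log2 fold change 4.78, SE 0.048, edgeR quasi-likelihood adjusted p = 5.88e-32). LGALS3BP, a secreted galectin-binding glycoprotein, rose from 14.04 ± 1.02 to 389 ± 10.5 CPM (SD, n = 3). CD209 and CLEC4M, neighbouring and closely related C-type lectin genes on chromosome 19, reached 41.8 ± 6.21 and 32.7 ± 1.78 CPM (SD, n = 3) in treated cells, from 10 and 33 counts in all untreated libraries together; the similar sequences leave the division of reads between them uncertain. ENHO, which encodes adropin, had no counts in untreated cells and 16.9 ± 0.744 CPM (SD, n = 3) in treated cells, at least 334-fold higher against a floor of 3 counts over the untreated group. The receptors ERBB3, PIGR and FCGR2A rose with log2 fold changes of 5.02, 4.93 and 4.49, the ETS transcription factor ETV7 with 4.45, and the cholesterol exporter ABCA1 with 4.39. In that order they had only 27, 21, 78, 38 and 56 counts in all untreated libraries together, so these fold sizes rest on a low base.

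Among the 10 largest falls, TMEM61 (chromosome 1, 54980792 to 54992293 on GRCh38) went from 28.6 ± 3.13 to 1.13 ± 0.195 CPM (SD, n = 3, log2 fold change -4.64, SE 0.16, edgeR quasi-likelihood adjusted p = 1.44e-19). C11orf95 fell from 13.005 ± 1.66 to 0.312 ± 0.173 CPM (SD, n = 3). CELSR2, an adhesion receptor gene of the cadherin family, had 596 counts in the untreated libraries together and 3 in the treated ones. BCAT1, which transfers amino groups from branched-chain amino acids, fell from 11.96 ± 2.04 to 1.16 ± 0.670 CPM (SD, n = 3). The lipase gene ABHD6, the adenylyl cyclase gene ADCY6, DIRAS1, STMN3, CHAC1 and PGM1 fell with log2 fold changes of -2.97, -2.85, -2.78, -2.77, -2.76 and -2.72.

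**Figure D2:**
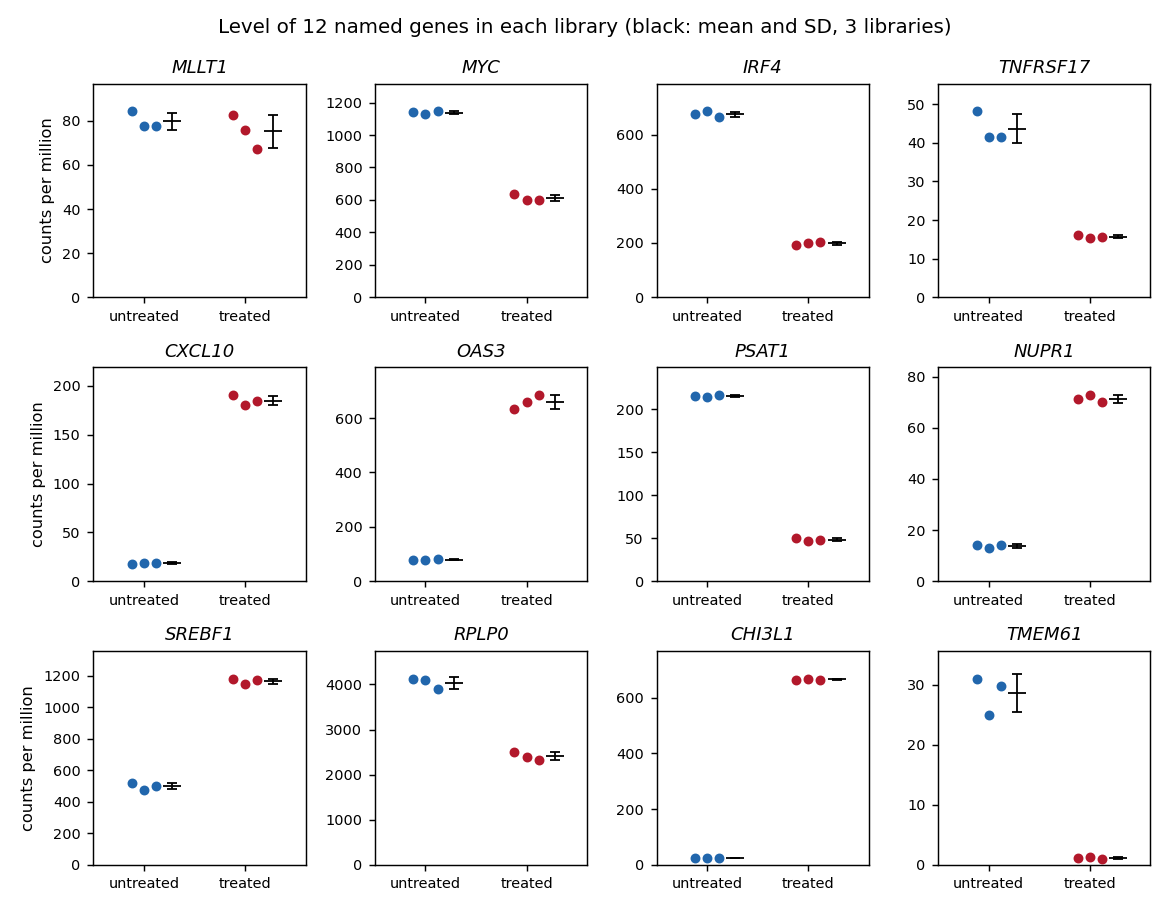
CPM (TMM-scaled) of 12 named genes in each of the 3 untreated (blue) and 3 treated (red) libraries, with the mean and SD of each group in black and every axis starting at 0. The groups overlap for MLLT1 and lie apart for the others drawn, with IRF4 near 675 CPM in untreated and 199 CPM in treated cells.

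The interferon response list rose as a whole (camera adjusted p = 8.15e-49), and the call held with an estimated correlation (adjusted p = 0.00307). All 47 members also rose adjusted over the list alone. OAS3, a sensor of double-stranded RNA, rose from 78.2 ± 2.34 to 659 ± 25.1 CPM (SD, n = 3, log2 fold change 3.08, SE 0.044, edgeR quasi-likelihood adjusted p = 3.14e-28). The antiviral genes MX2 and IFIT1 rose 3.77-fold and 3.87-fold, from 236 ± 3.22 and 105 ± 4.76 CPM (SD, n = 3). IFITM1 rose with a log2 fold change of 2.72, IFITM2 with 3.63 and IFITM3 with 4.01; the near-identical sequences of these 3 genes leave the value of each uncertain. The signal transducers STAT2 and IRF9 rose with log2 fold changes of 0.57 and 0.76. Of 19 antigen presentation genes, 14 rose and none fell over all genes tested, and 15 rose adjusted over the list alone (median log2 fold change 0.68, camera adjusted p = 1.61e-13). That call was lost with an estimated correlation (adjusted p = 0.0926 with an estimated correlation). TAP1, a peptide transporter, rose from 125 ± 3.11 to 318 ± 8.70 CPM (SD, n = 3), NLRC5, a regulator of class I genes, 2.44-fold, and HLA-E 1.88-fold, with reads of HLA genes uncertain where alleles and paralogs share sequence.

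NF-kB target genes rose as a list (camera adjusted p = 1.38e-06, 0.0457 with an estimated correlation), with 18 of 29 members higher and 2 lower over all genes tested, and 19 and 2 adjusted over the list alone. The members with the smallest p were CXCL10 and CCL5, chemokines that interferon also induces, at 18.3 ± 0.656 and 7.73 ± 0.943 CPM (SD, n = 3) in untreated and 185 ± 4.94 and 59.0 ± 3.09 CPM (SD, n = 3) in treated cells. BIRC3, an inhibitor of apoptosis, rose 2.55-fold, and TNFAIP2 fell with a log2 fold change of -1.15. The feedback genes NFKBIA and TNFAIP3 had log2 fold changes of 0.11 and 0.063 and did not pass.

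Genes of the integrated stress response, which ATF4 activates when amino acids run short or proteins misfold, fell as a list (median log2 fold change -0.99, camera adjusted p = 8.28e-27, 0.00549 with an estimated correlation). Adjusted over the list alone, 34 of 37 fell and 3 rose. The serine synthesis genes PSAT1, PHGDH and PSPH fell with log2 fold changes of -2.16, -2.05 and -1.48, PSAT1 from 215 ± 0.937 to 48.3 ± 1.29 CPM (SD, n = 3, edgeR quasi-likelihood adjusted p = 1.13e-23). ASNS, which makes asparagine, fell with -1.54, the glycine transporter SLC6A9 with -2.07, the cystine transporter SLC7A11 with -1.55 and ATF4 itself with -1.10. NUPR1, a stress-induced chromatin protein, and PPP1R15A, which restores translation after stress, rose with 2.38 and 0.42. DDIT3 had a log2 fold change of -0.29 and passed adjusted over the list alone but not over all genes tested (edgeR quasi-likelihood adjusted p = 0.0613).

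Of 34 genes of the unfolded protein response, 29 fell and none rose over all genes tested, and 30 fell adjusted over the list alone (median log2 fold change -0.27, camera adjusted p = 2.87e-12, 0.0200 with an estimated correlation). HERPUD1, ERN1, EDEM1 and HYOU1, which serve the degradation, sensing and folding of proteins in the endoplasmic reticulum, fell with log2 fold changes of -0.55, -0.52, -0.53 and -0.46. XBP1, a transcription factor of this response, went from 703 ± 17.6 to 662 ± 8.17 CPM (SD, n = 3) and did not pass over all genes tested (edgeR quasi-likelihood adjusted p = 0.0577), although it passed adjusted over the list alone and in 5 of the alternative settings. Of 20 heat shock genes, 3 rose and 8 fell over all genes tested and adjusted over the list alone, and the list was not called (camera adjusted p = 0.109). It was called without the filter on low counts (camera adjusted p = 0.0309) and after removal of GC and length trends (camera adjusted p = 0.0325). HSPD1, HSPH1, DNAJB1 and FKBP4 fell, with log2 fold changes of -0.51, -0.39, -0.31 and -0.27. Of 31 proteasome genes, 2 rose and 3 fell over all genes tested, 2 and 1 adjusted over the list alone, with no call for the list (camera adjusted p = 0.873). The balance turned with the setting: 6 rose and 1 fell with library size scaling, 3 and 1 without treated replicate 3, 2 and 6 with upper quartile scaling or the replicate number as a block, and 2 and 7 after removal of GC and length trends. PSMB2 and PSMA3 rose with log2 fold changes of 0.29 and 0.36, and PSMB5, a catalytic subunit, and PSMD8 fell with -0.27 and -0.17. The PSMD8 call was lost with library size scaling, without untreated replicate 1, without treated replicate 1 and without treated replicate 3.

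Cytosolic ribosomal protein genes fell as a list, by a median of 1.41-fold, with none higher, and 64 of 75 fell adjusted over the list alone (camera adjusted p = 5.99e-35). This call was lost with an estimated correlation (adjusted p = 0.114 with an estimated correlation). RPL3 fell from 3425 ± 49.9 to 1869 ± 75.6 CPM and RPLP0 from 4036 ± 126 to 2412 ± 94.3 CPM (SD, n = 3), and RPL5 and RPS6 had log2 fold changes of -0.81 and -0.74. Many processed pseudogenes copy these genes, so their reads are in part uncertain. MYC fell 1.86-fold (chromosome 8, 127735434 to 127741434 on GRCh38, SE of log2 0.036, edgeR quasi-likelihood adjusted p = 6.30e-18). Of 45 MYC target genes, 28 fell and 5 rose over all genes tested, 32 and 5 adjusted over the list alone (median log2 fold change -0.24, camera adjusted p = 1.97e-07, 0.0200 with an estimated correlation). The count of rising members was 3 without untreated replicate 2, untreated replicate 3 or treated replicate 3, 2 without treated replicate 2, 1 in both FPKM fits, and 3 with upper quartile scaling, without the filter on low counts or after removal of GC and length trends. SRM, which makes spermidine, fell from 400.1 ± 15.9 to 226 ± 13.3 CPM (SD, n = 3), CAD, which starts pyrimidine synthesis, fell 1.49-fold, and the mitochondrial chaperone gene HSPD1 fell 1.42-fold. TFRC, the transferrin receptor, rose 1.56-fold.

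IRF4 (chromosome 6, 391739 to 411447 on GRCh38) fell 3.39-fold (log2 fold change -1.76, SE 0.039, edgeR quasi-likelihood adjusted p = 8.70e-24). Of 29 plasma cell genes, 14 fell and 5 rose over all genes tested, 17 and 5 adjusted over the list alone (median log2 fold change -0.28, camera adjusted p = 6.57e-05). The median was -0.13 on log2(FPKM + 1). The list's call was lost with an estimated correlation (adjusted p = 0.0656 with an estimated correlation). Without untreated replicate 2, 3 rose. TNFRSF17, the surface receptor BCMA, fell from 43.7 ± 3.85 to 15.7 ± 0.435 CPM (SD, n = 3). The transcription factors MAF, POU2AF1 and PRDM1 fell with log2 fold changes of -0.73, -0.74 and -0.48, and CCND2, a G1 cyclin, with -0.81. IKZF1 and IKZF3, which encode Ikaros and Aiolos, rose with 0.71 and 0.24, and SDC1, the plasma cell marker CD138, rose with 0.15, a call lost without untreated replicate 2. The B cell marker list was not called (camera adjusted p = 0.616), with 5 of 16 members higher and 4 lower over all genes tested and adjusted over the list alone. Without untreated replicate 2, without treated replicate 2, with library size scaling, with the DESeq2 test and in both FPKM fits, 2 were lower, and after removal of GC and length trends 6 were higher and 6 lower. BLK and CD37 fell with log2 fold changes of -0.79 and -0.53, and CR2 and HLA-DRA rose with 0.59 and 0.87.

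Genes that ENL maintains in acute leukaemia were not called as a list (camera adjusted p = 0.616). Of 11 tested, 5 rose and 3 fell over all genes tested, and 6 and 3 adjusted over the list alone. MYC and BCL2 fell with log2 fold changes of -0.90 and -0.33, while MEF2C, CDK6 and MEIS1 rose with 0.40, 0.36 and 0.35. The MEIS1 call was lost in both FPKM fits, after removal of GC and length trends, without untreated replicate 2 and without treated replicate 1. MYB went from 12.5 ± 1.598 to 10.8 ± 1.29 CPM (SD, n = 3) and did not pass (edgeR quasi-likelihood adjusted p = 0.236), and HOXA9 had too few counts to be tested.

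Mitosis genes rose as a list (median log2 fold change 0.24, camera adjusted p = 9.09e-05), with 21 of 43 higher and none lower over all genes tested, and 22 higher and 1 lower adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.0926 with an estimated correlation). The median was 0.16 after removal of GC and length trends. CDK1, which drives entry into mitosis, rose from 43.6 ± 2.19 to 63.2 ± 3.75 CPM (SD, n = 3), and CDC25B, TOP2A and CCNB2 rose with log2 fold changes of 0.47, 0.34 and 0.41. Without treated replicate 1, with the replicate number as a block and in 4 other settings, 1 member fell. The DNA replication list was not called (camera adjusted p = 0.165), with 16 of 45 members higher and 4 lower over all genes tested, and 17 and 4 adjusted over the list alone. After removal of GC and length trends, 7 were lower. E2F2 and MCM6 fell with -0.80 and -0.43, and RRM2 and CLSPN rose with 0.55 and 0.73. Among 18 replication-dependent histone genes, 4 rose and 1 fell over all genes tested and adjusted over the list alone, without a call for the list (camera adjusted p = 0.366). With the DESeq2 test, without untreated replicate 2 or without treated replicate 1, 2 rose, while 2 fell without untreated replicate 1 and none did without untreated replicate 2 or 3 or without treated replicate 1 or 2. HIST1H1C, a linker histone gene, rose 1.45-fold. HIST1H2AG, HIST1H2AI and HIST1H2BD had log2 fold changes of 0.36, -0.50 and 0.18; all of these calls were lost without untreated replicate 2, and those of HIST1H2AI and HIST1H2BD also without treated replicate 1, without treated replicate 2 and in other settings.

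Of 26 cell cycle inhibitors and p53 targets, 7 rose and 7 fell over all genes tested and adjusted over the list alone, and the list was not called (camera adjusted p = 0.734). CDKN1A, the p53 target p21, was at 29.04 ± 2.05 and 29.2 ± 1.45 CPM (SD, n = 3) and did not pass (edgeR quasi-likelihood adjusted p = 0.972). CDKN2B rose from 2.27 ± 0.292 to 7.40 ± 1.37 CPM (SD, n = 3), while CDKN1B, CDKN1C and SESN2 fell with log2 fold changes of -0.39, -0.89 and -1.77. CCND1 and CCND3 rose with 0.25 and 0.62, the CCND1 call being lost after removal of GC and length trends and without untreated replicate 2. In the apoptosis list, 15 of 31 members rose and 6 fell over all genes tested, 17 and 6 adjusted over the list alone (camera adjusted p = 0.0412, and adjusted p = 0.270 with an estimated correlation). That call was also lost without untreated replicate 2 (camera adjusted p = 0.0512), without untreated replicate 3 (0.0744), without treated replicate 1 (0.0734), with at least 5 CPM in 3 libraries (0.0699) and after removal of GC and length trends (0.0540). The members moved both ways with respect to survival: the survival genes BCL2L1 and BCL2 fell with -1.03 and -0.33 and MCL1 rose with 0.43, while the death-promoting genes BMF and BCL2L11 rose with 0.79 and 0.15 and HRK fell with -2.26. The BCL2L11 call was lost after removal of GC and length trends.

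Fatty acid synthesis genes rose as a list (median log2 fold change 0.32, camera adjusted p = 7.47e-06; adjusted p = 0.0649 with an estimated correlation), with 13 of 17 higher and 2 lower over all genes tested and adjusted over the list alone. SREBF1, a transcription factor of lipid synthesis, rose from 499 ± 19.7 to 1164 ± 16.2 CPM (SD, n = 3), and SCD, FADS2 and ACACA rose 1.61-fold, 1.46-fold and 1.42-fold. Cholesterol synthesis genes went the other way, with 16 of 24 lower and 2 higher over all genes tested and adjusted over the list alone (median log2 fold change -0.25, camera adjusted p = 1.61e-04; adjusted p = 0.114 with an estimated correlation). SQLE and HMGCS1 fell with -0.79 and -0.78, and STARD4 rose with 0.89. Lysosome and autophagy genes rose as a list (median log2 fold change 0.10, camera adjusted p = 0.0150; adjusted p = 0.0937 with an estimated correlation), with 17 of 36 higher and 6 lower over all genes tested and adjusted over the list alone. Without treated replicate 2, and with library size scaling, 3 were lower. The median was 0.16 with library size scaling and 0.061 after removal of GC and length trends. The proteases CTSZ and CTSB rose 2.57-fold and 1.45-fold, and the autophagy receptor SQSTM1 1.61-fold.

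Transcripts of the mitochondrial genome rose as a list, 11 of 15 higher and none lower over all genes tested and adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 9.09e-05; adjusted p = 0.276 with an estimated correlation). Over the alternatives 8 to 12 were higher, with 8 by limma-voom. At most 1 was lower, as without treated replicate 2 and without robust dispersion. MT-ND1 went from 1216 ± 39.1 to 1588 ± 44.7 CPM (SD, n = 3). The nuclear genes of oxidative phosphorylation were not called (camera adjusted p = 0.516), with 5 of 51 higher and 10 lower over all genes tested and adjusted over the list alone. Without untreated replicate 1, and without treated replicate 3, 8 were higher, and with the replicate number as a block 9 were higher and 16 lower. The balance turned with library size scaling, with 10 higher and 8 lower, and was 7 higher and 16 lower after removal of GC and length trends. ATP5F1A, ATP5F1D and COX7C fell with -0.24, -0.31 and -0.27, and ATP5F1C rose with 0.27. Glycolysis and hypoxia genes were not called (camera adjusted p = 0.138), with 13 of 31 higher and 5 lower over all genes tested, and 14 and 5 adjusted over the list alone. Without untreated replicate 2, without treated replicate 2, with library size scaling and in both FPKM fits, 3 were lower, and 8 after removal of GC and length trends. The glucose transporter SLC2A3 rose 2.57-fold and PKM 1.33-fold, and PDK1, which inhibits pyruvate dehydrogenase, fell with a log2 fold change of -0.83.

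Of 22 myeloid markers listed, 8 could be tested. Of these, 7 rose and 1 fell over all genes tested and adjusted over the list alone (camera adjusted p = 2.15e-04, and 0.0649 with an estimated correlation). The 1 that fell was CST3, from 2320 counts in the untreated libraries together to 1816 in the treated ones. CD14, FCGR1A and MS4A7 could be tested only through their treated counts, which favours rises among the markers tested. CD14 rose from 0.445 ± 0.203 to 6.70 ± 0.586 CPM, CSF1R from 1.24 ± 0.191 to 8.004 ± 1.22 CPM and AIF1 from 2.24 ± 0.286 to 13.9 ± 0.846 CPM (SD, n = 3), and MRC1 rose 2.04-fold. The median log2 fold change of 2.53 shrank to 0.75 on log2(FPKM + 1). T and NK cell markers were not called (camera adjusted p = 0.415), with 3 of 11 higher and 4 lower over all genes tested and adjusted over the list alone. GZMA had no counts in untreated cells and was at least 22.1-fold higher in treated cells, at 1.12 ± 0.291 CPM (SD, n = 3). CD8B, high in this line, fell from 804 ± 15.3 to 583 ± 16.01 CPM (SD, n = 3), CD4 fell with a log2 fold change of -1.17, and NCAM1 rose with 0.31. Stromal and epithelial markers were not called (camera adjusted p = 0.734), with 3 of 9 higher and 2 lower over all genes tested and adjusted over the list alone. FN1, a matrix protein abundant in this line, fell 2.00-fold from 3759 ± 201 CPM (SD, n = 3), EPCAM fell with -0.38, and CDH1 and KRT8 rose with 0.83 and 0.71. Only 3 erythroid and megakaryocyte markers could be tested, too few for a list test. HBA2 had 115 counts in the untreated libraries together and 12 in the treated ones, with reads uncertain between it and its near-identical copy HBA1.

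Immediate early genes were not called (camera adjusted p = 0.165), with 8 of 29 higher and 3 lower over all genes tested and adjusted over the list alone. After removal of GC and length trends, 5 were lower. KLF2 fell from 44.6 ± 4.80 to 7.68 ± 1.12 CPM (SD, n = 3), ETV5 fell with a log2 fold change of -0.77, and DUSP6 and JUNB rose with 1.28 and 0.61. Of 25 genes often used as references, 10 rose and 6 fell over all genes tested, 12 and 6 adjusted over the list alone, and 3 fell without untreated replicate 1, without treated replicate 2 or with library size scaling. The list was not called (camera adjusted p = 0.165) except with library size scaling (adjusted p = 0.0487). B2M rose 1.601-fold.

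**Figure D3:**
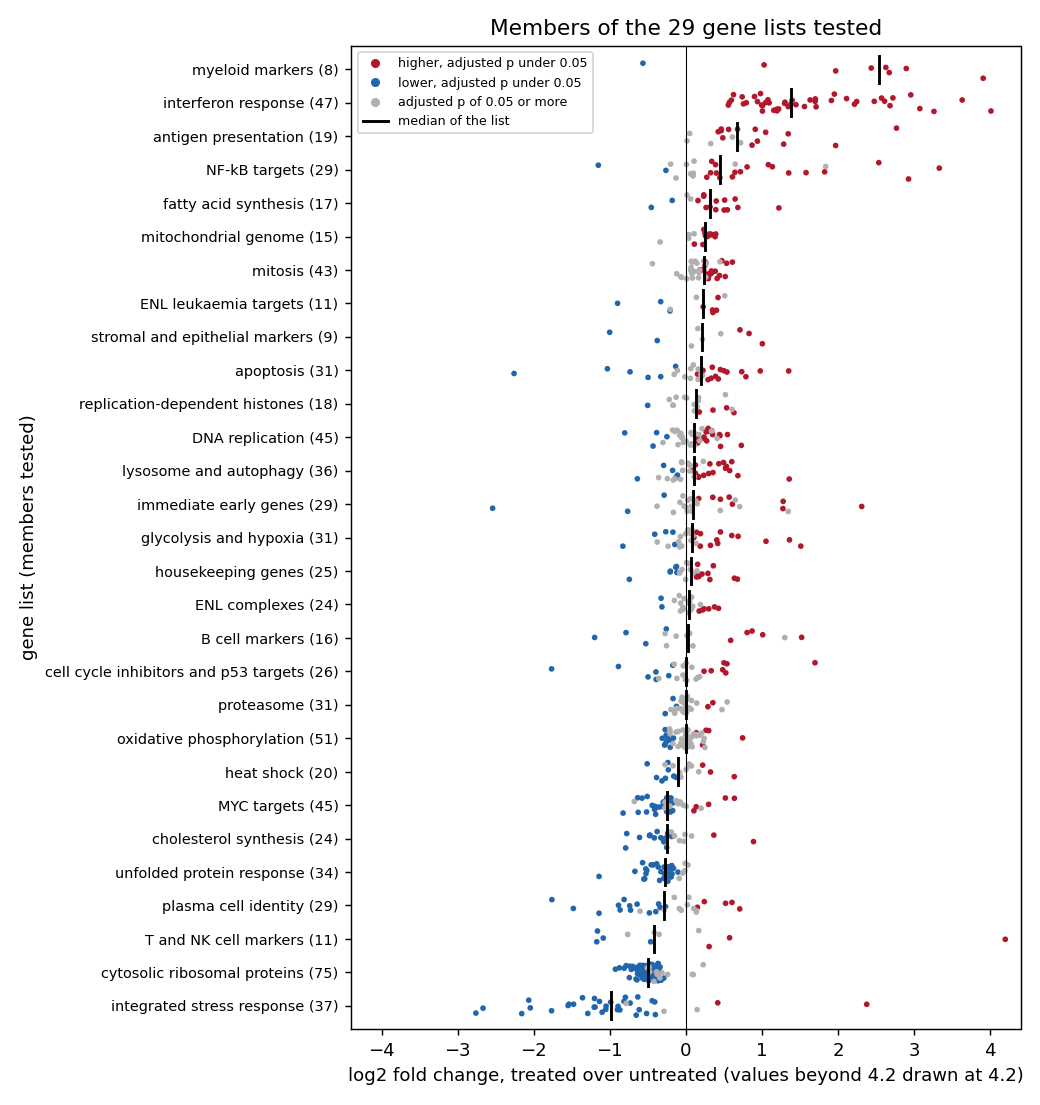
Log2 fold change in treated over untreated cells of each tested member of the 29 gene lists, ordered by the list's median (black bar), with red and blue points for members that rose or fell and grey for those that did not pass. Interferon response genes lie to the right of 0 throughout and integrated stress response genes mostly to the left, and 1 member beyond 4.2 is drawn at 4.2.

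In all, 15 of the 29 lists were called by camera with a preset correlation, 5 of these with an estimated correlation (interferon response, integrated stress response, unfolded protein response, MYC targets and NF-kB targets) and 23 by fry. A call lost with an estimated correlation need not come from correlation between genes. The estimates for the interferon response, myeloid, lysosome and MYC target lists were 0.0085, -0.065, -0.0094 and -0.017, below the preset 0.01. Even so, their unadjusted camera p rose, in that order from 2.81e-50 to 1.06e-04, 9.64e-05 to 0.0157, 0.00725 to 0.0356 and 4.08e-08 to 0.00275. For these lists the values argue against correlation between genes as what weakened the test. Fry asks whether a list's own genes move on balance in 1 direction; neither it nor its mixed form compares a list with other genes.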

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

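The removal of GC content and length trends was chosen after the data were seen. Over the alternatives, the count of changed genes ran from 4848 (threshold of 0.01) to 6942, and from 5549 to 6044 with each library left out in turn. Genes changed at least 2-fold numbered 1406 in the main test, 615 with at least 5 CPM in 3 libraries, where fewer genes were tested, and 404 on log2(FPKM + 1), where the pseudocount shrinks low genes. The 15 lists called became 5 with an estimated correlation and 23 with fry, which asks another question. Library size alone gave 61.0% of calls higher against 50.4%, with a median log2 fold change over all genes of 0.062, and removal of GC and length trends gave 44.5%, with a median of -0.031. MLLT1 did not pass in any setting and ran from -0.16 to -0.012 with each library left out; its log2 fold change was 0.033 (adjusted p = 0.673; 0.0644 to 0.904 over its alternatives) once GC and length trends were removed, and the cause was not tested. CDKN1A, which did not pass either, was at -0.0082 with upper quartile scaling and ran from -0.055 to 0.038 with each library left out, negative without untreated replicate 3 and without treated replicate 1; the cause was not tested. Over the named genes other than MLLT1, 2585 values under an alternative kept their direction and side of the threshold, 33 values of 9 genes lost the call, 5 values of XBP1 gained it and 3 of CDKN1A reversed. The test against a 1.5-fold change and the threshold of 0.01 were applied only to counts of genes and are not among these values. At 0.01, MEIS1, MLLT3 and PSMD8, among others, would not pass (edgeR quasi-likelihood adjusted p = 0.0149, 0.0202 and 0.0242). A gene that a setting's filter dropped has no value there. Without treated replicate 3, which stood apart on the second principal component, 47 interferon response genes rose, and 33 stress response, 28 unfolded protein response and 63 ribosomal protein genes fell. With the replicate block, 6942 genes changed. Whether the numbers pair the samples is unsettled. Deviations from the group means of samples with the same number correlated at 0.065, 0.0034 and 0.044. Samples with different numbers correlated at -0.060 to 0.014, and untreated replicate 2 correlated best with treated replicate 3. Of simulated 4-fold changes, 88% were recovered, with 200 genes changed in the simulation against 6312 called in the data. Adjustment is stricter when fewer genes change, so this rate is not the sensitivity of the real test.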

Other observations

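The gene groups of the next 2 paragraphs, and the tests of scaling, of interferon ligands and of myeloid cells, were chosen after the results were seen.

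All 18 translation factors and other mRNAs with a 5' terminal oligopyrimidine tract fell (median log2 fold change -0.45), a group taken up after the ribosomal protein genes and EEF1A1 had been seen to fall. EEF2, which moves the ribosome along the mRNA, fell with a log2 fold change of -0.83, and EEF1A1 from 35325 ± 290.1 to 23141 ± 778 CPM (SD, n = 3). Of 13 cytosolic aminoacyl-tRNA synthetases outside the stress list, 8 fell, none rose and 5 did not pass (camera adjusted p = 1.05e-04 over 34 lists; adjusted p = 0.0835 with an estimated correlation), among them QARS with -0.70 and CARS with -0.66. Of 78 mitochondrial ribosomal protein genes, 22 were lower, 3 were higher (MRPL19, MRPL39 and MRPL40) and 53 did not pass (median log2 fold change -0.11, camera adjusted p = 0.0339; adjusted p = 0.442 with an estimated correlation). Of 505 processed pseudogenes tested, 86 were lower and 18 higher.

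Of 13 chemokine genes tested, a family taken up because its members CXCL10 and CCL5 had risen, 11 rose and none fell. CCL8, CXCL5, CCL3 and CXCL11, at 0, 0.0153, 0.0989 and 0.201 CPM in untreated cells, could be tested only through their treated counts. This favours rises among the chemokine genes tested. CXCL9, which attracts T cells, rose from 17.1 ± 1.76 to 182 ± 2.81 CPM (SD, n = 3). CXCL11 and CCL3 rose with log2 fold changes of 4.99 and 2.54, to only 6.64 ± 0.608 and 0.615 ± 0.129 CPM (SD, n = 3). Of 11 immunoglobulin constant genes tested, 3 rose and 5 fell: the heavy chain genes IGHA1, IGHA2 and IGHE rose with log2 fold changes of 1.17, 2.03 and 2.38, from 70.3 ± 3.70, 35.1 ± 1.66 and 0.922 ± 0.166 CPM (SD, n = 3), while IGHG4 and IGHG2 fell with -0.78 and -0.59, the lambda light chain genes IGLC2 and IGLC3 with -0.76 and -0.73 and IGKC with -0.13. Reads of the near-identical genes among these are uncertain.

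The rise of all 47 interferon response genes was set against a difference in scaling and against interferon made by the cells themselves. The lowest median log2 fold change of the list over 4 scalings was 1.37. Those scalings moved the median over all genes tested only between -0.011 and 0.062, too little to undo such a rise. They show that the choice among them does not matter here, but cannot test a change in RNA per cell. Interferon genes together had 101 counts in treated and 98 in untreated libraries, a ratio of 0.889 after scaling to library size (95% exact binomial interval 0.667 to 1.19). The lambda interferon genes alone had 32 and 5 counts (ratio 5.52, 2.14 to 18.2) and the others 69 and 93 (ratio 0.640, 0.462 to 0.884). These intervals leave out the spread between libraries. Among the others, IFNG had 9, 9 and 26 counts in untreated replicates 1 to 3 and 9, 6 and 11 in treated ones. It was the only interferon gene tested and did not pass (edgeR quasi-likelihood adjusted p = 0.192). A source in lambda interferon, or in an interferon pulse before day 4, cannot be told apart from induction without interferon at these counts. A response to the treatment itself may underlie the rise and stays open as an untested hypothesis.

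The fall of ribosomal protein genes was set against GC content or transcript length and against scaling. After GC and length trends were removed the median log2 fold change was -0.53. This argues against GC content or transcript length as the whole cause, as far as the longest annotated transcript of a gene measures them. That transcript need not be the one counted, so an effect of the length of the counted mRNA was not tested. The highest median over the 4 scalings was -0.44. These scalings differ too little to undo such a fall. All use relative counts, so a change in RNA per cell was not tested. Reads shared with processed pseudogenes stay open, because the counting of reads with several matches is not given in the sources used here. A hypothesis is that lower MYC, or lower synthesis of amino acids, may go with the fall, and it was not tested.

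The rise of 7 of 8 myeloid markers was set against myeloid cells in the treated cultures. LYZ, TYROBP and FCER1G, abundant in monocytes and macrophages, went together from 0.0305 to 0.532 CPM while CD14 and CSF1R together went from 1.69 to 14.7 CPM, a ratio of gains of 0.0386 (at most 0.0566 at the upper 95% Poisson bound of the treated counts). This argues against such cells as the source of the CD14 and CSF1R transcripts. Expression of these genes by the myeloma cells may be the source and was not tested.

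ENL acts with elongation factors, so a further hypothesis, set before its result was seen, was that long genes would fall more. It was not borne out: the 1270 protein-coding genes with the longest genomic span (at least 165 kb) had a median log2 fold change higher by 0.073 than other genes of similar expression (permutation p = 1e-04, the smallest that 10000 permutations can give). The median was -0.051 in the tenth of genes with the shortest span and 0.063 in the tenth with the longest. The permutation exchanged genes of similar expression, so its p takes genes as independent and does not measure the spread between libraries. The span test was not repeated after removal of GC and length trends or without the ribosomal protein genes.

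The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real one, 6312 genes changed, 3179 higher and 3133 lower, and 1406 changed at least 2-fold, where the highest other split gave 0 by the edgeR quasi-likelihood test for each of these counts (146 to 451 genes at an unadjusted p under 0.05). For lists the real split gave 15 camera calls and the highest other 13, with the preset correlation. Every other split holds treated and untreated libraries in both groups, so the treatment effect becomes spread within groups. Neither their counts of 0 nor their camera calls therefore tell what chance alone would give.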
